A study of Homo sapiens with 6 samples.

How the data were processed

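RNA was sequenced from 2 human cancer cell lines, SK-Mel-147 (melanoma) and SCOV3 (ovarian carcinoma), that had been infected with the lentiviral pLV-Puro vector, empty or carrying FOXQ1 cDNA, and selected with puromycin, per the labels' protocols. Per the labels, total RNA was made into libraries with the Illumina TruSeq RNA kit. The titles give 6 libraries in 4 groups: 2 SK-Mel-147 vector, 2 SK-Mel-147 FOXQ1, 1 SCOV3 vector and 1 SCOV3 FOXQ1. Groups were taken from the titles, although the V and F marks in the names of the deposited files follow the replicate number of the SK-Mel-147 titles and not their construct.

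The deposited values are raw read counts per gene, 1 table per library. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.9 to GRCh38 and counted with HTSeq. The strand setting, the annotation release and any filter are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, cannot be told apart. All 6 tables hold the same 58037 gene IDs in the same order, followed by 5 summary rows that are not genes and were left out of every total. Reads in no annotated gene made up 18.07 to 93.5% of all reads in these tables, and ambiguous reads 0.4 to 6.54%. The row for reads aligned to several places was 0 in each library. Of the IDs, 57433 were matched to a symbol through GENCODE 29, 53688 of them with the same version number, and 56948 were found in a separate table of gene names.

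Gene totals ranged from 4070353 to 61460698 counts. A count of 0 was given a floor of 3 counts, over a library or over a group as stated, which is 0.0488 to 0.737 CPM for single libraries. For a group, "at least" folds pool the counts and TMM-scaled totals of its libraries, so deeper libraries weigh more. Intervals at the 95% level are exact (Clopper-Pearson) and, like the floors, cover counting error only.

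The 4 replicated comparisons were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. They were SK-Mel-147 FOXQ1 against vector (4 libraries), SK-Mel-147 replicate 2 against replicate 1 with the construct of the titles as a term (4 libraries), SCOV3 against SK-Mel-147 with the construct as a term (6 libraries, and at least a 2-fold difference) and the difference of the FOXQ1 response between lines (the interaction term, 6 libraries). In the interaction the spread came from SK-Mel-147 alone, and the lone SCOV3 libraries were assumed to vary like those. The same holds for the lines without the SCOV3 vector library. With the construct as a term, log2 fold changes of that fit set SCOV3 FOXQ1 against the 2 SK-Mel-147 libraries labelled FOXQ1 alone. Its "at least" folds pool all 4 SK-Mel-147 libraries. In the replicate-number and interaction fits the prior degrees of freedom were infinite, so each gene took the spread pooled over genes. SCOV3 FOXQ1 against vector has 1 library per group and was described without a test: log2 ratios of TMM-scaled CPM with a prior count of 2, genes at least 2-fold apart with at least 50 counts in the higher library, and each list's median as a percentile among 10000 random lists matched on mean expression.

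Lists of 31 gene groups were fixed before the data were examined, as were the groups, the comparisons, the tests and the rule for named genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 2), with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the libraries and fry were run beside it. In each tested comparison the named genes were the 12 largest rises and 12 largest falls past the threshold with a mean of at least 50 counts and a symbol, up to 4 members of lowest p in each list, and FOXQ1, CDH1, CDH2, MITF and CTNNB1. For the untested comparison they were the 12 largest ratios each way and up to 4 members of largest ratio in each list. Changes are log2 fold changes ± the standard error, and levels are TMM-scaled CPM as mean ± SD (n = 2) unless said otherwise. The standard error was derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. It therefore adds nothing to the change and its p-value.

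Alternatives were DESeq2 size factors, library size alone, no filter, a mean of at least 50 counts, the DESeq2 1.42.0 Wald test, limma voom, leaving out each SK-Mel-147 library, a replicate block, no group term, all 6 libraries in 4 groups, the other divisions of the 4 SK-Mel-147 libraries, count minimums of 10 and 200, and prior counts of 0.5 and 5. Thinning to equal depth, limma voom, leaving out a SCOV3 library and the gene lists under other libraries and scalings were added after the data were seen. The comparison of the lines without the SCOV3 vector library was reported in full for the same reason.

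The fits were tested on simulated data with 200 changed genes at the real means and library sizes. For SK-Mel-147 FOXQ1 against vector, edgeR recovered 60% of 2-fold and 93% of 4-fold changes over 19660 genes, with 10 unchanged genes called. The same test recovered 67% and 99% over 19689 genes for the replicate numbers (10 unchanged genes called), and 57% and 98% over 23546 genes for the lines without the SCOV3 vector library (13 called). For the lines with all 6 libraries it recovered 0% of either size over 22043 genes, and for the interaction 2% of 2-fold and 62% of 4-fold changes over 30729 genes (5 called). Apart from the changed genes, each gene was simulated with the same mean in all libraries. No simulated library was therefore as unlike the others as SCOV3 vector, and these rates do not cover fits that include it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.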

Results

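The series measured messenger RNA in cells labelled SK-Mel-147 (melanoma) and SCOV3 (ovarian carcinoma) carrying either the empty lentiviral vector or FOXQ1 cDNA, to find genes that respond to FOXQ1, a forkhead transcription factor, in 2 cell lineages. There were 2 libraries of each construct in SK-Mel-147 and 1 of each in SCOV3, so the SCOV3 pair has no replicate. Gene totals in SK-Mel-147 were 12722825 and 6384773 counts in the libraries labelled vector and 46082523 and 36194454 in those labelled FOXQ1. The SCOV3 libraries held 4070353 counts (vector) and 61460698 (FOXQ1). Reads in no annotated gene made up 93.5% of the SCOV3 vector library and 18.07 to 44.08% of the other 5. Ranked expression was correlated across genes with a mean of at least 50 counts over all libraries. Spearman's rho was 0.99 and 0.989 within the SK-Mel-147 groups and 0.966 to 0.975 between them. It was 0.181 to 0.212 between the SCOV3 vector library and each other library.

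FOXQ1 itself (ENSG00000164379.6, chromosome 6, 1312440 to 1314748, plus strand, GRCh38) was read first, as a check of the labels. SK-Mel-147 vector replicate 1 had 0 FOXQ1 counts and vector replicate 2 had 194 (30.4 CPM of the gene total). The libraries labelled FOXQ1 had 0 counts in replicate 1 and 577 (15.9 CPM) in replicate 2. FOXQ1 was at least 129-fold higher in vector replicate 2 than in vector replicate 1, and at least 245-fold higher in FOXQ1 replicate 2 than in FOXQ1 replicate 1, each against a floor of 3 counts per library. In SCOV3 the vector library had 1 FOXQ1 count and the FOXQ1 library 1053 (17.1 CPM), a ratio of 69.7 with a counting interval of 12.5 to 2760. The FOXQ1 counts therefore go against the titles of 2 of the 4 SK-Mel-147 libraries, and groups of that line are named below as the libraries labelled FOXQ1 or vector.

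**Figure D1:**
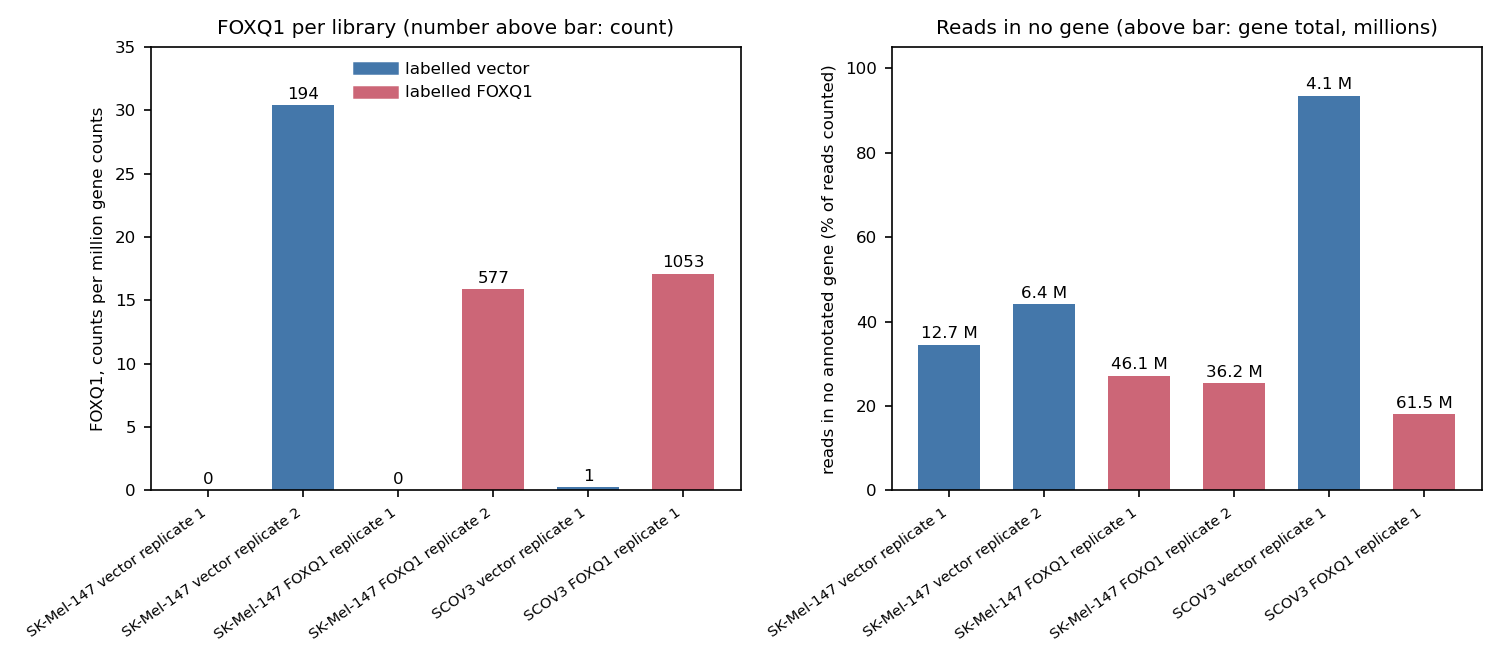
Left, FOXQ1 as CPM of the gene total in each library, with the count above each bar; right, reads in no annotated gene as a percentage of reads, with the gene total above each bar (blue, labelled vector; red, labelled FOXQ1). FOXQ1 was at 0 counts in SK-Mel-147 replicate 1 of both labels and at 194 and 577 counts in replicate 2, and the SCOV3 vector library stood at 93.5% of reads in no gene.

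The comparison of SK-Mel-147 libraries labelled FOXQ1 with those labelled vector addresses the response of melanoma cells to FOXQ1, and it rests on labels that the FOXQ1 counts go against in 2 libraries. Interferon-stimulated genes, which are induced by viral RNA and interferons, rose in the libraries labelled FOXQ1. IFI44L went from 2.47 ± 1.78 to 186 ± 4.91 CPM (log2 fold change 6.42 ± 0.32, adjusted p = 1.95e-06, edgeR with Benjamini-Hochberg adjustment), and MX1, an antiviral GTPase, from 1.84 ± 1.2 to 97.4 ± 23.8 CPM (5.91 ± 0.33). Cytokine genes rose as well: IL6, an inflammatory cytokine, went from 0.673 ± 0.736 to 115 ± 77 CPM (7.78 ± 0.64, adjusted p = 2.76e-05, edgeR, Benjamini-Hochberg). The chemokine gene CXCL10 had 0 counts in both vector libraries and 4.41 ± 2.37 CPM in those labelled FOXQ1, at least 30.4-fold higher against 3 counts over the group. FOXQ1 itself did not pass the test in this comparison (log2 fold change -0.71 ± 1.5, adjusted p = 0.802, edgeR, Benjamini-Hochberg); its value turned with the library left out. It was 10.96 without vector replicate 2 (adjusted p = 8.96e-20), -11.12 without FOXQ1 replicate 2 (1.45e-27), -1.82 without vector replicate 1 (1.64e-07) and 0.36 without FOXQ1 replicate 1 (0.889), of which 10.96 and -11.12 are fitted against libraries at 0.

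Of 20179 genes tested, 1652 passed the threshold, 1061 higher and 591 lower in the libraries labelled FOXQ1 (5109 at an unadjusted p under 0.05; biological coefficient of variation 15.2%). Scaling by library size alone gave 732 higher and 942 lower and moved the median change of all genes by -0.118. Among the largest rises, FDCSP was at least 53.7-fold, the keratin gene KRT6B at least 44.5-fold, QPCT at least 25.3-fold, the chemokine gene CXCL11 at least 21.9-fold and the bradykinin receptor gene BDKRB2 at least 18.7-fold higher, each from 0 counts in the vector group. C1S, a complement protease (7.57 ± 0.42, adjusted p = 2.35e-06, edgeR, Benjamini-Hochberg), IFI27 (7.03 ± 0.54) and OAS2, which senses double-stranded RNA (6.95 ± 0.45), followed. The largest falls included the mitochondrial ribosomal RNA MT-RNR1 (-2.84 ± 0.3, adjusted p = 0.000167, edgeR, Benjamini-Hochberg), from 837 ± 466 to 117 ± 12.6 CPM, and UCP2, a mitochondrial carrier (-2.21 ± 0.26), from 17.9 ± 5.76 to 3.92 ± 0.495 CPM. The olfactory receptor pseudogene OR51K1P (-2.57 ± 0.26) and gene OR51I1 (-2.32 ± 0.26) fell too. MTATP6P1 (-1.87 ± 0.18) shares reads with its near-identical copy MT-ATP6 and is uncertain. CDH2 (0.47 ± 0.17, adjusted p = 0.0987), MITF (-0.38 ± 0.21, 0.286) and CTNNB1 (0.30 ± 0.14, 0.198) did not pass the test, and CDH1 had 2 to 13 counts per library and was not tested.

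By list, 28 of 29 interferon-stimulated genes rose and 0 fell (29 and 0 adjusted over the list alone). IFIT3 was at 3.67 ± 0.21 and IFIH1 at 3.22 ± 0.2, and the exception, HERC5, chosen after its values were seen, was at 1.96 ± 0.68 (adjusted p = 0.0973). The list passed camera (adjusted p = 3.61e-24, Benjamini-Hochberg over the lists) and had adjusted p = 0.507 with an estimated correlation. Of 23 NF-kB and cytokine genes, 21 rose and 0 fell (23 and 0 adjusted over the list alone), among them ICAM1, a leukocyte adhesion molecule (5.38 ± 0.38), the chemokine gene CCL20 (4.8 ± 0.51) and PTGS2 (4.73 ± 0.54). IL1A (0.94 ± 0.35) and LIF (0.64 ± 0.2), chosen after their values were seen, did not pass. The list had a camera adjusted p = 8.14e-12, and adjusted p = 0.514 with an estimated correlation. Of 25 p53 target genes, 16 rose and 0 fell (24 and 0 adjusted over the list alone). Among these were MDM2, the ubiquitin ligase for p53, from 200 ± 6.19 to 485 ± 11.4 CPM (1.28 ± 0.14), and the cell cycle inhibitor CDKN1A, from 157 ± 1.91 to 396 ± 83.1 CPM (1.33 ± 0.17). The p53 list had a camera adjusted p = 2.35e-12, and adjusted p = 0.448 with an estimated correlation. It was also the 1 list that fry called, at an adjusted p = 0.0354.

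Matrix and adhesion genes rose in part. Of 21 collagen and matrix genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), including LUM (2.53 ± 0.19), FN1, which encodes fibronectin (2.25 ± 0.25), COL5A2 (1.5 ± 0.15) and FBN1 (1.42 ± 0.15). The count was 8 without vector replicate 1 and 8 with library size alone. Of 24 mesenchymal and EMT genes, 8 rose and 0 fell (13 and 1 adjusted over the list alone), with the cadherin gene CDH11 at 4.59 ± 0.32, TAGLN at 2.94 ± 0.32 and SNAI2, a repressor of epithelial genes, at 1.84 ± 0.19. Of 14 integrin genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with ITGA1 at 2.68 ± 0.16 and ITGB8 at 1.34 ± 0.21. Camera gave these lists adjusted p = 1.12e-05, 3.19e-05 and 0.000428, and adjusted p = 0.514, 0.514 and 0.507 with an estimated correlation. Of 12 neural and Schwann markers, 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them the myelin gene MBP (2.75 ± 0.48), SOX2, NES and, chosen after its values were seen, L1CAM (adjusted p = 0.00288, camera, and adjusted p = 0.507 with an estimated correlation).

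Mitochondrially encoded genes fell: 10 of 13 fell and 0 rose (12 and 0 adjusted over the list alone), with MT-ATP6 at -1.96 ± 0.16, MT-ND4L at -1.2 ± 0.16 and MT-ND4 at -1.13 ± 0.15. The list had a camera adjusted p = 3.54e-06, and adjusted p = 0.507 with an estimated correlation. Of these, 6 fell and 1 rose without vector replicate 1. The share of gene counts on mitochondrial genes was 1.06 and 0.92% in the libraries labelled vector and 0.44 and 0.45% in those labelled FOXQ1. Of 26 DNA replication and G1/S genes, TYMS (-0.67 ± 0.16), MCM6 (-0.61 ± 0.16) and MCM10 (-0.51 ± 0.14) fell and 0 rose (4 and 0 adjusted over the list alone). Of 13 replication-dependent histone genes, H2BC4 fell (-0.67 ± 0.14; 7 adjusted over the list alone). Both lists had a camera adjusted p = 0.00174, and adjusted p = 0.514 with an estimated correlation. None of 31 cytosolic ribosomal protein genes was called by edgeR, over all genes or adjusted over the list alone, although camera called the list lower (adjusted p = 0.0159, median -0.184; adjusted p = 0.655 with an estimated correlation). Of 6 endothelial markers, ROBO4 (-1.2 ± 0.18) and TIE1 (-0.91 ± 0.17) fell and 0 rose, the same counts adjusted over the list alone (adjusted p = 0.0238, camera, and adjusted p = 0.514 with an estimated correlation).

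Smaller groups of genes rose in the libraries labelled FOXQ1 in lists of other pathways. Of 19 dedifferentiated melanoma markers, 6 rose and 0 fell (10 and 1 adjusted over the list alone), with INHBA at 1.99 ± 0.19, WNT5A at 1.46 ± 0.22 and the neural crest receptor gene NGFR at 1.44 ± 0.29. Of 19 TGF-beta target genes, 4 rose, TGFB2, BHLHE40 and COL1A1 among them, and 0 fell (8 and 0 adjusted over the list alone). Of 23 hypoxia and glycolysis genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone), with P4HA2 at 1.49 ± 0.24 and the glucose transporter gene SLC2A1 at 0.92 ± 0.16. Camera gave these lists adjusted p = 0.0074, 0.00195 and 0.00349, and adjusted p = 0.514, 0.507 and 0.655 with an estimated correlation.

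The remaining lists did not pass camera. Melanocyte lineage regulators had SNAI2 higher and CREB3L2 lower (-0.63 ± 0.16) of 14, the same counts adjusted over the list alone, and the list's median (-0.0893) and mean (0.091) differed in sign (adjusted p = 0.917). Of 11 melanin synthesis and melanosome genes only SLC24A4 (-1.17 ± 0.3) was called over all genes (2 higher and 2 lower adjusted over the list alone; median 0.0284, mean -0.113, adjusted p = 0.973). Epithelial junction and keratin genes had CLDN1 (4.68 ± 0.46), F11R (1.38 ± 0.24), PKP3 and JUP higher of 15 (5 and 0 adjusted over the list alone; adjusted p = 0.168). Of 27 mitosis and G2/M genes, the proliferation marker MKI67 (-1.02 ± 0.16) and CDC20 (-0.71 ± 0.16) fell, 0 rose and the counts adjusted over the list alone were the same (adjusted p = 0.0501). Of 18 unfolded protein response genes, CALR, DNAJB9 and SEL1L rose (5 and 0 adjusted over the list alone; adjusted p = 0.0501; 0 with library size alone). Of 20 immediate early genes, IER3, ATF3, BTG2 and SOCS3 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0611).

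Wnt and beta-catenin target genes had TNFRSF19, BAMBI and CCND1 higher and TCF7L2 lower (-0.89 ± 0.22) of 16 (4 and 2 adjusted over the list alone; adjusted p = 0.371). Among 13 beta-catenin and Groucho cofactors, BCL9 (-0.91 ± 0.2) and TCF7L2 fell (0 and 4 adjusted over the list alone; median 0.101, mean -0.17, adjusted p = 0.387). YAP and TAZ target genes had GADD45A, TGFB2 and NUAK2 higher and ASAP1 lower of 21 (4 and 2 adjusted over the list alone; adjusted p = 0.156). MAPK pathway output genes had IER3, DUSP4 and CCND1 higher of 18 (4 and 1; adjusted p = 0.374). Of 23 ATF4 and amino acid response genes, STC2, ATF3 and CEBPB rose and ASNS (-0.91 ± 0.15), PHGDH (-0.83 ± 0.14) and PSAT1 fell, CEBPB and PSAT1 being named after their values were seen (5 and 3 adjusted over the list alone; adjusted p = 0.83). SREBF2 (-0.69 ± 0.15) was the 1 gene called of 23 cholesterol synthesis genes, also adjusted over the list alone (adjusted p = 0.177). Among markers of other cell types, LUM and COL1A1 rose of 8 fibroblast markers (4 and 1 adjusted over the list alone; adjusted p = 0.461), CD24 and MUC1 of 12 ovarian carcinoma markers (2 and 0; adjusted p = 0.181) and KRT6A (at least 8.8-fold, from 0 counts) of 8 keratinocyte markers (1 and 1; median 0.0272 but a camera direction downward, adjusted p = 0.962). None of 4 immune cell markers was called by edgeR over all genes (1 and 0 adjusted over the list alone; adjusted p = 0.962).

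Calls of several lists rested on single libraries. Without vector replicate 1, camera no longer called the dedifferentiated (adjusted p = 0.125; 3 rose), TGF-beta (0.0929; 0 rose), hypoxia (0.192; 3 rose) lists, nor the replication (0.129), histone (0.0929), ribosomal (0.324) and endothelial (0.135) lists. Without FOXQ1 replicate 2 the hypoxia (0.138) and ribosomal (0.147) lists were lost, and the endothelial list was lost without vector replicate 2 (0.239) or FOXQ1 replicate 1 (0.0884). Lists gained were cholesterol synthesis without vector replicate 2 (0.00205) or FOXQ1 replicate 1 (0.00792), mitosis without FOXQ1 replicate 1 (0.0015), unfolded protein response (0.0263) and YAP and TAZ targets (0.0263) without FOXQ1 replicate 2, and immediate early genes without vector replicate 2 (0.0298) or FOXQ1 replicate 2 (0.00797). The count of called genes was 1043 without vector replicate 1 and 3056 without FOXQ1 replicate 2. The p-values measure the spread between these libraries alone, which may be technical, and the groups also differed in depth. Reads in no gene (34.51 and 44.08% in the libraries labelled vector, 27.18 and 25.44% in those labelled FOXQ1) and the share of gene counts on 7SL and 7SK genes (5.4 and 4.46% against 6.91 and 6.99%) moved with the label as well.

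**Figure D2:**
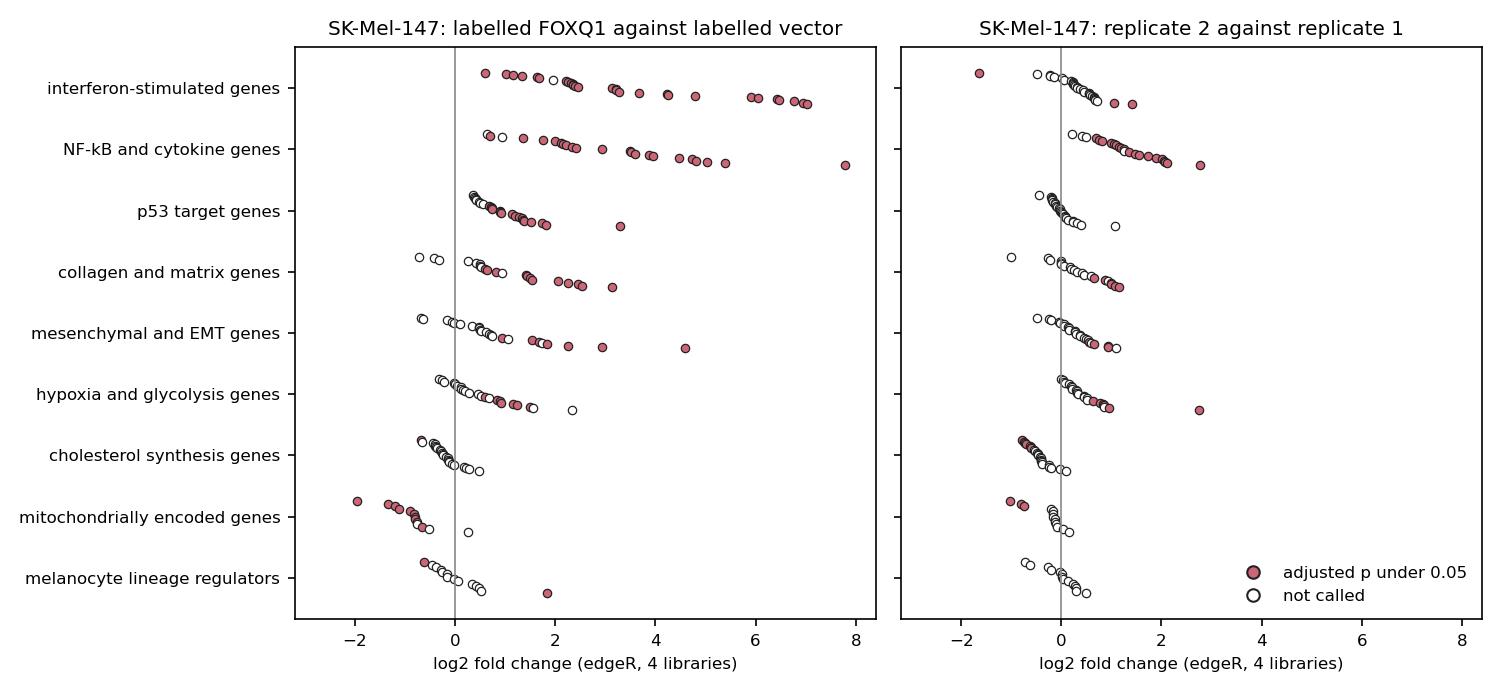
Log2 fold change of each member of 9 gene lists in SK-Mel-147, labelled FOXQ1 against labelled vector (left) and replicate 2 against replicate 1 (right); filled points have an adjusted p under 0.05. In the labelled comparison 28 of 29 interferon-stimulated and 16 of 25 p53 target genes rose, against 3 and 0 between the replicate numbers, while NF-kB and cytokine genes rose in both (21 and 19 of 23).

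The comparison of SK-Mel-147 libraries numbered 2 with those numbered 1, with the label as a term, measures whatever the numbers carry, and FOXQ1 follows the numbers: it was at least 354-fold higher in the libraries numbered 2 (adjusted p = 4.75e-85, edgeR, Benjamini-Hochberg). Inflammatory genes were higher in the libraries numbered 2. CXCL8, a chemokine that draws neutrophils, was at 18.2 and 267 CPM in vector replicates 1 and 2 and at 711 and 2520 CPM in FOXQ1 replicates 1 and 2 (log2 fold change 2.77 ± 0.18, adjusted p = 1.24e-49, edgeR, Benjamini-Hochberg). IL1B (2.05 ± 0.17), CXCL1 (2.11 ± 0.18), CSF2 (2.07 ± 0.3), CSF3 (2.21 ± 0.33) and PTGES, a prostaglandin synthase (2.16 ± 0.21), rose as well. HMGCS1 (-0.79 ± 0.16) and IDI1 (-0.74 ± 0.16), which encode enzymes of cholesterol synthesis, fell.

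In total 309 of 20179 genes passed the threshold, 231 higher and 78 lower in the libraries numbered 2 (1579 at an unadjusted p under 0.05). Of the 309, 297 had the same sign in both labels, 181 of them at least 1.5-fold in each. The calls were fitted to these same pairs, so this agreement follows in large part from the selection and is not separate evidence. CCN4, a secreted Wnt target (2.51 ± 0.33), TMEM158 (2.29 ± 0.23) and GFPT2 (2.12 ± 0.21) were among the largest rises. Falls were largest for copies of the 5.8S ribosomal RNA (RNA5-8SN2, -2.15 ± 0.17), near-identical and so uncertain one from another. Lower too were DHRS2 (-2.1 ± 0.34), BST2, an antiviral membrane protein (-1.65 ± 0.33), COL11A1 (-1.56 ± 0.34) and KRT87P (-1.55 ± 0.24). BST2 fell in the libraries labelled FOXQ1 only (log2 ratio -1.69, against 0.55 in those labelled vector), and DHRS2 mostly there (-2.26 against -0.18); these 2 genes, COL11A1 and FOS were not called by the DESeq2 Wald test. The fall of FOS (-1.41 ± 0.22) also came from the libraries labelled FOXQ1 (73.6 to 8.23 CPM), since those labelled vector went from 24.1 to 34.6 CPM. CDH2 (0.27 ± 0.16, adjusted p = 0.787, edgeR, Benjamini-Hochberg), MITF (-0.21 ± 0.22, 0.983) and CTNNB1 (-0.01 ± 0.16, 1) were not called.

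Of 23 NF-kB and cytokine genes, 19 rose and 0 fell (22 and 0 adjusted over the list alone); NFKB1, CCL20, LIF and TNF, the 4 that did not pass, were named after their values were seen. Of 23 cholesterol synthesis genes, 5 fell and 0 rose (16 and 0 adjusted over the list alone): HMGCS1, IDI1, MSMO1 (-0.73 ± 0.17), INSIG1 (-0.71 ± 0.16) and, chosen after its values were seen, SQLE. Of 23 hypoxia and glycolysis genes, 6 rose and 0 fell (10 and 0 adjusted over the list alone), with CA9 at 2.74 ± 0.4, NDRG1 at 0.95 ± 0.17 and VEGFA at 0.83 ± 0.17. Interferon-stimulated genes had IFI27 (1.42 ± 0.22), IFI6 (1.06 ± 0.22) and OAS3 (0.65 ± 0.18) higher and BST2 lower of 29 (10 and 1 adjusted over the list alone). Camera gave these lists adjusted p = 6.33e-27, 1.95e-11, 9.2e-08 and 7.04e-07. Collagen and matrix genes had 6 higher and 0 lower of 21 (9 and 1 adjusted over the list alone; 0.000136), with COL6A2 at 1.16 ± 0.21 and THBS2 at 1.07 ± 0.17. Mesenchymal and EMT genes had FN1, ITGB3 and MMP2 higher of 24 (7 and 0; 0.000576). Mitochondrially encoded genes had MT-ND6 (-1.03 ± 0.18), MT-ND3 and MT-ATP8 lower of 13 (the same counts adjusted over the list alone; 0.00748). Camera also called the dedifferentiated melanoma markers higher (TNC, NGFR, WNT5A and SMAD3 of 19; 0.0213), the fibroblast markers higher (MMP2 of 8; 0.0216) and the ribosomal protein genes lower (RPS16 of 31; 0.0213). All 10 called lists had adjusted p = 0.688 with an estimated correlation. None of 25 p53 target genes, 11 melanin genes and 14 melanocyte lineage regulators was called by edgeR over all genes. Immediate early genes had IER3 higher and FOS and FOSB lower of 20 (adjusted p = 0.977, camera). FOSB, like FOS, was lower only in the libraries labelled FOXQ1 (log2 ratio -2.14, against 0.24 in those labelled vector).

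The 2 SK-Mel-147 comparisons overlapped. In all, 120 genes were higher in both the libraries labelled FOXQ1 and those numbered 2, against 12.1 for independent lists, and both are fitted to the same 4 libraries. With 1 residual degree of freedom and infinite prior degrees of freedom, the edgeR calls by number rest on the spread pooled over genes and not on each gene's own. The DESeq2 Wald test gave 107 genes, with FOXQ1 at an adjusted p = 0.329 and CXCL8 at 0.207 (Benjamini-Hochberg) although their log2 fold changes stayed at 11.5 and 2.85. CXCL1 was not called by it either (2.25, adjusted p = 0.177). Without the label as a term edgeR gave 0 (187 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0.

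SCOV3 was compared with SK-Mel-147 to set the lineages apart, with all 6 libraries as planned and again without the SCOV3 vector library, since that library stood far from every other. That these libraries hold SCOV3 ovarian carcinoma cells rests on the labels alone and is in doubt: SCOV3 FOXQ1 had the keratinocyte gene KRT5 at 1960 CPM of the gene total and the ovarian gene PAX8 at 1.2 CPM, although 7 of 20 ovarian carcinoma markers reached 50 CPM. Without the SCOV3 vector library, log2 fold changes set SCOV3 FOXQ1 against the SK-Mel-147 libraries labelled FOXQ1 alone, since the construct was a term. The SCOV3 FOXQ1 library was higher than SK-Mel-147 in epithelial genes. CDH1, the epithelial cadherin, stood at 389 CPM against 0.284 ± 0.00827 and 0.299 ± 0.0962 CPM in the libraries labelled vector and FOXQ1 (log2 fold change 10.35). MPZL2, an adhesion molecule of epithelial cells, was at least 4930-fold higher, from 0 counts in all 4 SK-Mel-147 libraries. SOX10, the melanocyte and neural crest regulator, was at least 2240-fold lower, from 0 counts in SCOV3 FOXQ1, as was the cancer-testis gene MAGEA4 (at least 1800-fold). CDH2, the neural cadherin, was lower (-3.72 ± 0.26).

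The spread of this fit came from SK-Mel-147 alone, and the lone SCOV3 library was assumed to vary like those. In it, 7493 of 24790 genes passed with at least a 2-fold difference, 3948 higher and 3545 lower in SCOV3. The connexin gene GJB2 was at least 4410-fold, SERPINB13 at least 1970-fold and the cornified envelope gene SPRR1B at least 1950-fold higher; CKMT1A and CKMT1B are near-identical copies and are uncertain one from another. Of 25 epithelial junction and keratin genes, 23 were higher and 0 lower (24 and 0 adjusted over the list alone), with KRT7 at 8.8 ± 0.24, ESRP1, a splicing factor of epithelial cells, at 10.64 ± 0.33 and EPCAM at 9.19 ± 0.36 (camera adjusted p = 1.8e-14, and adjusted p = 0.382 with an estimated correlation). Of 11 keratinocyte markers, 10 were higher and 0 lower, the same adjusted over the list alone, with KRT5, a basal keratin, at 12.68 ± 0.29, SFN at 12.1 ± 0.31 and DSG3 at 9.96 ± 0.27 (4.75e-07, and adjusted p = 0.44 with an estimated correlation). Of 19 ovarian carcinoma markers, 12 were higher and 3 lower (13 and 3 adjusted over the list alone). MUC16, which encodes the CA125 antigen, was at least 699-fold higher, while PAX8 (-1.88 ± 0.38) and WT1 (-4.39 ± 0.51), like EMX2 chosen after their values were seen, were the genes lower (0.00183, and adjusted p = 0.495 with an estimated correlation).

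Melanocyte lineage regulators had 8 lower, SOX5 (-7.71 ± 0.44) and ZEB2 (-3.7 ± 0.25) among them, and ERBB3, SOX9 and TFAP2A higher of 15 (the same adjusted over the list alone; 0.0139, and adjusted p = 0.495 with an estimated correlation); the 3 higher genes were named after their values were seen. MITF was lower than in the libraries labelled FOXQ1 by less than 2-fold (-0.85). In the scaling of all 6 libraries it stood at 6.82 CPM in SCOV3 FOXQ1. The libraries labelled FOXQ1 stood at 12.3 ± 2.18 CPM and those labelled vector, which do not enter that fold, at 16 ± 0.542 CPM. Interferon-stimulated genes had a median log2 fold change of -1.95, with MX2 at -6.73 and HERC5, named after its values were seen, higher. The reference here is the libraries labelled FOXQ1, where this list was itself raised (median 3.14 over the libraries labelled vector). Lower than those libraries therefore does not mean lower than the libraries labelled vector. In the planned fit with all 6 libraries the list had a median of 0.18 and was not called (camera adjusted p = 0.278). Neural and Schwann markers had 10 lower, NCAM1 at -9.82 ± 0.42, and 3 higher of 14, ERBB3 and MBP among them (0.00183, and adjusted p = 0.495 with an estimated correlation). ATF4 and amino acid response genes were called higher (9 higher and 2 lower of 23; ALDH1L2 at 3.58 ± 0.26), as were mitosis genes (PLK1 higher of 27), and unfolded protein response genes lower (6 of 18; HSPA5 at -1.86 ± 0.23). Their camera adjusted p were 0.00162, 0.035 and 0.0016, and adjusted p = 0.495, 0.863 and 0.593 with an estimated correlation. CTNNB1 (0.21 ± 0.19, adjusted p = 0.434) and FOXQ1 (1.26 ± 1, adjusted p = 0.351) were not called by edgeR with Benjamini-Hochberg adjustment.

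**Figure D3:**
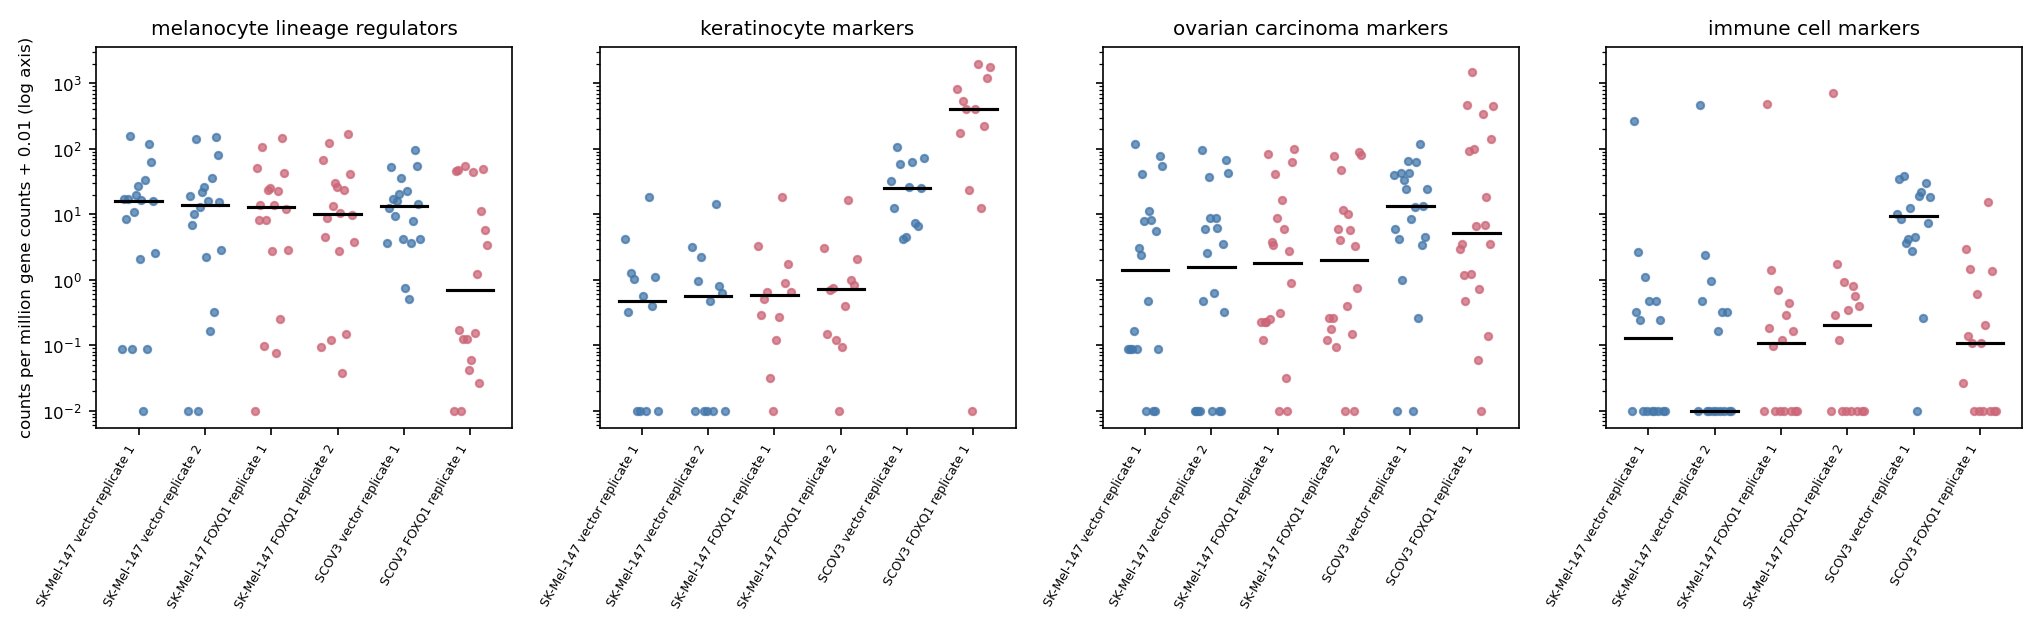
CPM of the gene total plus 0.01, on a log axis, of each melanocyte lineage regulator, keratinocyte marker, ovarian carcinoma marker and immune cell marker in each library; black lines are medians (blue, labelled vector; red, labelled FOXQ1). Keratinocyte markers had a median of 412 CPM in SCOV3 FOXQ1 and 0.472 to 0.718 CPM in SK-Mel-147, and immune cell markers a median of 9.35 CPM in the SCOV3 vector library.

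The planned fit with all 6 libraries had a biological coefficient of variation of 70.4% and called 835 of 22399 genes, 707 higher and 128 lower in SCOV3; all 835 were also called without the SCOV3 vector library. CDH1 was called (8.85 ± 1.1, adjusted p = 0.0224, edgeR, Benjamini-Hochberg), and CDH2 (-4.94 ± 1.1, 0.0716), MITF (-0.74, 0.371), CTNNB1 (-0.91, 0.555) and FOXQ1 (-0.62, 0.911) were not. MPZL2 had 0 counts in all 4 SK-Mel-147 libraries and stood at 21.8 and 158 CPM in SCOV3 vector and FOXQ1. The homeobox gene ALX1 had 0 counts in both SCOV3 libraries and 10.5 to 14.8 CPM in SK-Mel-147. Of 24 epithelial junction and keratin genes 7 were higher (16 adjusted over the list alone; camera adjusted p = 7.85e-07), and of 11 keratinocyte markers 6 (10 adjusted over the list alone; 7.42e-07); 0 were lower in either. Fibroblast markers had DCN, FAP, COL1A1, COL1A2 and COL3A1 higher and LUM lower of 12 (0.00221), and ovarian carcinoma markers had WFDC2 and MUC16 higher of 17 (0.0104). Camera called 8 further lists lower, the ribosomal protein genes (8.69e-05) and unfolded protein response genes (0.000108) among them, with 0 genes called by edgeR in either. All 12 lists had adjusted p = 0.842 with an estimated correlation, and the median of all genes shifted by 0.149 with DESeq2 size factors and by 0.253 with library size alone. Without any single SK-Mel-147 library edgeR called 0 genes (2350 to 2674 at an unadjusted p under 0.05); with all libraries the DESeq2 Wald test called 5057 and limma voom 1460.

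SCOV3 FOXQ1 against vector addresses the response of carcinoma cells, and with 1 library per group it has no test. Genes of abundant housekeeping transcripts were far lower in the vector library: GAPDH had a log2 ratio of 5.79 (fold interval 51.3 to 59.5, or 17.5 to 20.4 on gene totals alone), the translation factor gene EEF1A1 6.89 (110 to 128, or 37.8 to 43.6) and the ribosomal protein gene RPL8 7.26. GAPDH and EEF1A1 were chosen after their values were seen. GAPDH stood at 175 CPM of the gene total in SCOV3 vector and 3180 to 3720 CPM in the other 5 libraries. Epithelial keratins followed, with KRT7 at 7.49 (149 to 222) and KRT14 at 7.12 (115 to 172), and CDH1 went from 135 counts to 21272 (4.93, fold interval 25.8 to 36.4, or 8.81 to 12.5 on gene totals alone). TMM scaling makes every fold of this comparison 2.93 times that on gene totals, and the intervals do not cover that choice. MT-ND6, a mitochondrial complex I gene, was lower in the FOXQ1 library (-4.63, ratio 0.0372 to 0.0435).

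Of 20828 genes with at least 50 counts in the higher library, 17708 were at least 2-fold apart, 11132 higher and 6576 lower in SCOV3 FOXQ1, with a median log2 ratio of 1.36; library size alone gave 7653 higher and 8840 lower with a median of -0.174. The balance also turned with the count minimum, to 12846 higher and 16001 lower at 10 counts and 9963 higher and 1583 lower at 200. TSC22D3 had 5357 counts in the FOXQ1 library and 0 in the vector library, on gene totals at least 118-fold higher. PROSER2 (at least 106-fold), PPP1R14C (at least 102-fold) and RHOD (at least 82.3-fold) also had 0 counts there. The neuronal genes GRIN2B (at least 506-fold) and LHX9 (at least 416-fold) and the pseudogene GOLGA6L25 (at least 647-fold) were lower with TMM scaling, with 0 counts in the FOXQ1 library. CDH2 had a log2 ratio of 4.37, CTNNB1 3.75 and MITF 0.20 (59 against 350 counts, ratio 0.87 to 1.54). The direction of MITF turned with the scaling, from 14.5 to 5.69 CPM of the gene total. All 31 ribosomal protein genes were at least 2-fold higher (median 6), as were all 13 histone genes (5.42) and all 11 keratinocyte markers (5.50). The same held for all 27 mitosis genes (4.38) and 23 of 24 epithelial genes (4.77), each of these lists at percentile 100 of matched random lists. With abundant housekeeping transcripts far lower in the vector library, such percentiles cannot tell a response of a list from the state of that library. Mitochondrially encoded genes lay at percentile 0 (median -1.94, 10 of 13 lower). Endothelial markers had a median of -4.23 (6 of 8 lower, percentile 17.6) and immune cell markers of -2.91 (6 of 7 lower, percentile 12.2). Interferon-stimulated genes lay at percentile 50 (median 1.29, or -0.247 with library size alone) and NF-kB and cytokine genes at 84.8 (2.92); ovarian carcinoma markers had a median of 3.06, or 2.18 with genes at 0 counts set to their bound.

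The difference of the response between lines asks whether the change with label in SCOV3 differed from that in SK-Mel-147. Its direction inherits both the SK-Mel-147 labels and the lone SCOV3 vector library. The prior degrees of freedom of this fit were infinite, so its p-values rest on the spread pooled over genes and not on each gene's own. The wide spread of FOXQ1 within each SK-Mel-147 label is thus not carried by its standard error or p-value below. In the SCOV3 pair the housekeeping genes GAPDH and EEF1A1, chosen after their values were seen, had log2 ratios of 5.79 and 6.89. CTNNB1 (3.75) and CDH1 (4.93) were below both there, so a larger rise in SCOV3 is not particular to these genes. CTNNB1, which encodes beta-catenin, rose more in SCOV3 (3.24 ± 0.31, adjusted p = 3.18e-24, edgeR, Benjamini-Hochberg), as did CDH1 (4.77 ± 0.86), CDH2 (3.77 ± 0.45), KRT7 (6.57 ± 0.41) and RPL8 (7.25 ± 0.36). MT-ND6 (-5.11 ± 0.33) moved the other way, and MITF did not pass (0.37 ± 0.43, adjusted p = 0.496; -1.15, adjusted p = 0.0239, among genes with a mean of at least 50 counts, and negative but not called with both other scalings). FOXQ1 passed (8.13 ± 0.73, adjusted p = 3e-27), on 1 count in the SCOV3 vector library and FOXQ1 counts that go against the SK-Mel-147 labels; without vector replicate 2 it was -3.47 (adjusted p = 0.453). It did not pass among genes with a mean of at least 50 counts (6.64, adjusted p = 0.233) or by the DESeq2 Wald test (7.67, adjusted p = 0.394). In all 20614 of 32086 genes passed, 10716 higher and 9898 lower. DESeq2 size factors gave 9252 and 11329, library size alone 7682 and 12889, with medians of all genes shifted by -0.599 and -1.23.

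All 31 ribosomal protein genes, all 13 histone genes, all 26 replication genes and all 27 mitosis genes were higher in the difference (24 of the replication genes with either other scaling), as were 19 of 25 epithelial genes and 8 of 12 keratinocyte markers, with COL17A1 at 6.18 ± 0.38. None of these lists had a gene lower, and counts adjusted over the list alone were the same. Camera gave them adjusted p = 4.57e-10, 1.18e-05, 1.53e-08, 1.53e-08, 1.02e-05 and 0.0126, and adjusted p = 0.388, 0.355, 0.355, 0.388, 0.355 and 0.355 with an estimated correlation. Endothelial markers had 9 lower and EGFL7, chosen after its values were seen, higher of 12 (0.0124, and adjusted p = 0.355 with an estimated correlation), and immune cell markers 7 lower of 13 (0.0111, and adjusted p = 0.402 with an estimated correlation). Interferon-stimulated genes had 16 lower and 5 higher of 29 (0.499, not called), and mitochondrially encoded genes 8 lower and 3 higher of 13 (0.772, not called). The reads of the SCOV3 vector library, 93.5% of them in no gene, enter every one of these differences.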

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

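Tests chosen only after the results were seen were those of exchanged titles, of material carried between libraries, of the FOXQ1 transcript level and of a shared round, and the thinning behind the test of depth was added after the data were seen; the tests of sparse sampling and genomic DNA were written before their own results were seen.

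FOXQ1 in SK-Mel-147 was detected in replicate 2 of both labels and at 0 counts in replicate 1 of both, so 2 of the 4 libraries match their titles as given. Material of FOXQ1 replicate 2 carried into vector replicate 2 is argued against, since the FOXQ1 CPM of vector replicate 2 was 1.91 times that of FOXQ1 replicate 2 (counting interval 1.61 to 2.25). With the titles of vector replicate 2 and FOXQ1 replicate 1 exchanged, 4 of 4 libraries match, which is consistent with a mislabelling of these 2 libraries, an explanation found from the same counts. The marks in the names of the deposited files follow the replicate number in the same way, while a number series in those names parts the libraries titled vector from all others. Ranked expression over all genes follows the labels as given instead, at Spearman's rho 0.99 and 0.989 within them and 0.966 to 0.975 between them. If the titles were exchanged, the response to FOXQ1 would be the difference between the replicate numbers and not that between the labels. That difference called 309 genes only with the titles as given kept as a term. Without that term edgeR called 0.

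Interferon-stimulated and NF-kB genes were higher in the libraries labelled FOXQ1, a direction that rests on those labels. A difference in depth is argued against, because after thinning to equal depth the 52 genes of the 2 lists kept a median log2 fold change of 2.91 (3.04 before), with 44 called (49 before). The FOXQ1 transcript level as the only cause is argued against too: between FOXQ1 replicate 1 and vector replicate 1, both at 0 FOXQ1 counts, the interferon genes had a median log2 ratio of 2.65 (quartiles 2.28 to 5.4) and the NF-kB genes of 3.23 (quartiles 1.37 to 4.57). A shared culture, preparation or sequencing round of each group cannot be told apart from the label, since the groups also differed together in depth (lowest over highest 2.84) and in the number series of the file names. A part of the FOXQ1 level is not excluded, since 19 of 23 NF-kB genes and 3 of 29 interferon genes also rose with the replicate number, which FOXQ1 follows, and an effect of the construct without its transcript was not tested.

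The SCOV3 vector library was singled out as a signal outside the gene counts, with 93.5% of its reads in no annotated gene. Sparse sampling of RNA like that of the SCOV3 FOXQ1 library is argued against. That library thinned to the same gene total correlated with itself at Spearman's rho 0.972, against 0.38 observed over 30174 genes. These genes had a mean of at least 1 CPM over the SCOV3 pair. The same pair was at 0.182 over genes with a mean of at least 50 counts in all libraries, the set used in the Results. Reads from genomic DNA stay open, because among 19663 genes with 0 counts in the 5 other libraries 30.4% had a count here and counts followed exon length at rho 0.481; both missed the levels set beforehand as support (over 50% and over 0.5), and neither reached those set against it (under 10% or under 0.2). Genomic DNA as the only source is argued against, since the 500 most counted protein-coding genes of the SCOV3 FOXQ1 library had 49.2 counts per kb of exon against 6.94 in 1783 silent ones, a ratio of 7.09. No biological explanation was tested for this library.

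The difference of the FOXQ1 response between lines was singled out as a difference between groups, with 20614 of 32086 genes past the threshold.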

How the results depend on the processing

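Voom, thinning, the fits without a SCOV3 library and the gene lists under other scalings or without a library were chosen only after the results were seen. Of the alternatives for named genes, 1040 stayed on their side of the threshold, 160 lost the call, 15 gained it and 3 reversed. Values not called could still change sign, as FOXQ1, CTNNB1 and MITF did. Of those for the comparisons and their gene lists, 42 counts stayed within 1.5 times, 19 fell further and 8 rose further. A further 2, of the untested SCOV3 pair, moved by more than 1.5 times. Where a count moved, the cause was not tested. For SK-Mel-147 FOXQ1 against vector, 2820 genes were called without a filter, 2728 with all 6 libraries in 4 groups and 871 after thinning. Leaving out 1 library gave 1043 to 3056, with the lone library of a group assumed to vary like the other group. The 2 other divisions of the 4 libraries were libraries numbered 2 against libraries numbered 1, and vector replicate 1 and FOXQ1 replicate 2 against the other pair. They gave 0 and 0 with edgeR, 1 and 0 with DESeq2, and 0 and 0 with limma voom. FOXQ1 ranged from -11.12 (without FOXQ1 replicate 2) to 10.96 (without vector replicate 2). For replicate 2 against replicate 1, the DESeq2 Wald test gave 107 and the fit with no group term 0; leaving out a library was not run, with no residual degree of freedom left. For SCOV3 against SK-Mel-147, the DESeq2 Wald test gave 5057, limma voom 1460, and fits without 1 library 0 (any SK-Mel-147 library) to 25799 (without SCOV3 FOXQ1), with 7493 without SCOV3 vector. For the difference of the FOXQ1 response between lines, genes with a mean of at least 50 counts gave 11661 with MITF at -1.15, and FOXQ1 ranged from -3.47 to 18.76 without 1 library. For SCOV3 FOXQ1 against vector, count minimums of 10 and 200 gave 28847 (mostly lower) and 11546 (mostly higher). Of the gene lists, a correlation estimated from the libraries called 0 in each of the 4 tested comparisons; fry called 1, 0 and 3 in SK-Mel-147 FOXQ1 against vector, replicate 2 against replicate 1 and SCOV3 against SK-Mel-147, and 27 (camera 19) in the difference of the FOXQ1 response between lines. Without 1 library, camera called 8 to 16 lists in SK-Mel-147 FOXQ1 against vector. Depth limits the libraries labelled vector most, where 3 counts are 0.236 and 0.47 CPM in SK-Mel-147 and 0.737 CPM in SCOV3.

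With the replicate number as a block, 3131 genes were called in SK-Mel-147 FOXQ1 against vector (1758 higher, 1373 lower). Deviations of same-numbered libraries correlated at 0.21 over 14142 genes, 0.181 without FOXQ1, and 2 pairs do not show that same-numbered libraries were paired, though FOXQ1 itself follows the number.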

Other observations

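All of the contrasts below come from the comparison of the lines without the SCOV3 vector library, which was chosen only after the results were seen, and from marker levels per library. The log2 fold changes of this comparison set SCOV3 FOXQ1 against the SK-Mel-147 libraries labelled FOXQ1 alone. Its p-values rest on the spread within SK-Mel-147, with the lone SCOV3 library assumed to vary like the libraries of that line.

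ITGB4, the hemidesmosome integrin, was higher in SCOV3 FOXQ1 than in SK-Mel-147 (log2 fold change 9.69 ± 0.27, adjusted p = 5.42e-23, edgeR, Benjamini-Hochberg), as were F3, which encodes tissue factor (7.43 ± 0.25), and the growth factor response gene EGR1 (5.57 ± 0.31). Their lists were not called by camera: integrin genes had 5 higher and 3 lower of 15 (adjusted p = 0.408), YAP and TAZ target genes 1 and 5 of 21 (0.174) and immediate early genes 9 and 1 of 21 (0.101). Of 18 Wnt and beta-catenin target genes, 9 were higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.242, camera), with MYC at 4.38 ± 0.22, RNF43 at 6.03 ± 0.35 and LEF1 at -4.15 ± 0.31. Mesenchymal and EMT genes went both ways, 6 higher and 11 lower of 25 (adjusted p = 0.174, camera), with COL1A1 at 4.51 ± 0.28, VIM at -3.29 ± 0.22 and MMP2, a matrix protease, at -5.45 ± 0.32.

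Basal keratinocyte genes stood high in SCOV3 FOXQ1: KRT5 at 1960 CPM of the gene total, KRT14 at 1190 and TP63, a regulator of basal cells, at 173, with 9 of 12 keratinocyte markers at 50 CPM or more. The ovarian lineage genes PAX8 (1.2 CPM) and WT1 (0.13 CPM) were low in the same library, and MUC16 was at 18.7 CPM. Of 20 ovarian carcinoma markers 15 reached 1 CPM and 7 reached 50 CPM. Among those 7, KRT7, KRT8, KRT18, EPCAM and CLDN4 are also in the list of epithelial genes. In the SCOV3 vector library KRT5 was at 63.1 CPM, PAX8 at 33.4 and MUC16 at 120. That library also held counts of markers of other cell types: 14 of 16 immune cell markers and 12 of 12 endothelial markers reached 1 CPM there, with PTPRC at 8.6 and PECAM1 at 37.1 CPM. In the 5 other libraries 2 to 4 immune cell markers and 2 to 5 endothelial markers did so. Detection in the SCOV3 vector library was not particular to these cell types. There, 14 of 14 fibroblast markers, 13 of 14 neural and Schwann markers and 17 of 20 melanin genes reached 1 CPM too. Counts were found for 35027 genes in that library and for 25856 to 33145 in the 5 others. Counts followed exon length at Spearman's rho 0.702 in the SCOV3 vector library and 0.568 to 0.585 elsewhere.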
